A study of Homo sapiens with 4 samples.

How the data were processed

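Gene expression was measured by RNA sequencing in 4 libraries of MV4-11 cells, an established human acute myeloid leukaemia line. Per the labels' protocols, cell pellets were frozen on dry ice, RNA was extracted with Trizol, and libraries were made from total RNA with the NEBNext Ultra RNA kit. Whether poly(A) RNA was selected or ribosomal RNA was depleted is not given in the sources used here, nor is the way in which side and main populations were separated. The submitters' processing notes name bcl2fastq 2.17.1.14, cutadapt 1.3, Trimmomatic 0.30 and HTSeq 0.6.1 and the build hg19, without the role or order of each program. The aligner, the gene annotation and the use of strand in counting are not given in the sources used here.

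Each library had 1 table of 57905 Ensembl genes, which pairs every identifier with a symbol. The deposited count of each gene is a raw read count per the file headers, and the values were whole numbers whose sums differed between libraries. The deposited FPKM of each gene, per the file headers, was the count per kilobase of exonic length and per one-millionth of the library's summed counts. This was tested on the values: over genes with at least 200 counts, the recomputed FPKM differed from the deposited one by at most 0.005. The summed counts include mitochondrially encoded genes, so the FPKM of every other gene is lowered where those genes take a large share. FPKM was used here only as an alternative to the counts.

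Total counts were 16196557 for untreated side-population cells, 12351220 for untreated main-population cells, 13645919 for treated side-population cells and 14808352 for treated main-population cells. Outside mitochondrially encoded genes, the same libraries held 15782845, 7026125, 12967428 and 4964593 counts. The shares of counts carry 95% exact Clopper-Pearson intervals. A gene with 0 counts was given a floor of 3 counts. Reads are not independent molecules, so these intervals and floors cover counting error only.

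Each of the 4 groups had 1 library, and the labels give no replicates. A model with population and treatment as additive terms was fitted to the counts with edgeR 4.0.16 (quasi-likelihood test, limma 3.58.1, R 4.3.3) after scaling by trimmed mean of M values (TMM). The fit has 1 residual degree of freedom. Its spread is the disagreement of the populations about the effect of treatment, pooled across genes with 13.1 prior degrees of freedom, and it is not a spread between replicates. Genes with at least 1 CPM in at least 2 libraries were tested, which left 14457. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are given with an approximate standard error (SE), their size over the square root of the quasi-likelihood F statistic.

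Single libraries were also compared as log2 ratios of TMM-scaled counts over effective library size (CPM) with a prior count of 2. These ratios have no test, and their 95% intervals are exact conditional binomial intervals of the raw counts, without the prior count. The difference of the treatment ratios between populations leaves no residual degrees of freedom and has no test either. Ratios were counted at a log2 size of at least 1.

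The tests, the alternatives, 32 gene lists, 8 sets of markers of other cell types and the rule for named genes were fixed before the data were examined. Named genes have a named symbol and a mean of at least 5 CPM. For treatment, they are the 12 genes with the highest and the 12 with the lowest fold change among called genes with a log2 ratio of at least 1 in the same direction in both populations. For population, they are the 10 highest and 10 lowest by the same rule across treatments. For the difference of treatment ratios, they are the 6 highest and 6 lowest whose counting interval leaves out 0. FLT3, MYC, MCL1, ABCG2, ABCB1, CXCR4 and CD34 are always named, as are up to 4 members per list with the largest fold change. Where a list had 5 or fewer called members, those outside the rule were named after their values were seen. A few genes that these rules select are not reported here. Of the listed symbols, PECAM1 was not found in the files.

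For each list, called members are counted over all tested genes and with p values adjusted over the list alone. The median log2 ratio of its members was placed among 10000 random lists of the same size drawn from 20 bins of mean expression. That percentile describes these libraries and is not a test. A list of nuclear-retained long RNAs and one of small RNAs without a poly(A) tail were added after the libraries had been seen. Gene types and GC contents came from GENCODE 29, which holds 52338 of the 57905 identifiers and uses another build, so no coordinates were taken from it.

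The procedure was tested on simulated data, as counts for the 14457 genes, with 50 genes changed at each of 4 fold sizes. The changed genes all had a mean of at least 5 CPM. For treatment, 28% of genes changed by a log2 fold of 1 were called, 94% at 2, 100% at 3 and 100% at 4, with 11 of 14257 unchanged genes called. For population, the shares were 18%, 90%, 100% and 100%, with 8 unchanged genes called. Counts were drawn independently for each gene, at the dispersion fitted to these libraries. The rates therefore do not cover an effect shared by the genes of 1 library, or a disagreement between populations beyond that dispersion.

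The alternatives were DESeq2 size factors, total counts and upper-quartile scaling in place of TMM. They also included the DESeq2 1.42.0 Wald test, no filter beyond 1 count, a filter of 5 CPM and an added minimum fold. Further ones were a fit without the other factor, each library left out in turn, no mitochondrially encoded genes, prior counts of 0.5 and 10, and FPKM with a pseudocount of 1. Protein-coding nuclear genes alone and a crossed split of the libraries were added after the data had been seen. With a library left out, the fit had 1 factor, and the lone library of a group was assumed to vary like the others. Fits of 1 factor leave the effect of the other factor in their spread or their values. Lost calls and turned signs in them do not by themselves show dependence on 1 library. Reads shared between near-identical copies make the values of mitochondrial, histone, small nuclear RNA, ribosomal protein and HSPA1A or HSPA1B genes uncertain, as do overlapping and antisense genes.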

Results

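RNA was sequenced from MV4-11 cells, a leukaemia line with an internal tandem duplication of FLT3 and the MLL-AF4 fusion. The libraries form 4 groups of 1 library each, from side-population and main-population cells, untreated or treated for 24 h with AC220 and HHT together. AC220 (quizartinib) inhibits the FLT3 kinase, and HHT (homoharringtonine) inhibits translation elongation. Neither drug was sequenced alone. A side population is usually sorted by its export of a DNA dye through ABC transporters, but the labels do not say how these cells were separated. Without replicate libraries, no difference below has been set against a spread between replicates.

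Total counts ran from 12351220 to 16196557 per library. Mitochondrially encoded genes took 2.55% of counts in untreated side cells (95% exact interval 2.547 to 2.562) and 43.1% in untreated main cells (43.09 to 43.14). After treatment they took 4.97% in side cells (4.961 to 4.984) and 66.5% in main cells (66.45 to 66.5). The mitochondrial ribosomal RNAs alone held 0.442% and 21.7% of counts in untreated side and main cells, and 1.41% and 43.6% in treated side and main cells. The nuclear RNA MALAT1 held 0.092% and 1.01% of counts in untreated side and main cells, and 0.0436% and 1.65% after treatment. The small nuclear RNA RN7SK held 0.000407%, 0.178%, 0.0194% and 0.267% of counts in the same order. These differences in composition run along the population comparison and, within each population, along treatment for the mitochondrial genes and RN7SK.

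**Figure D1:**
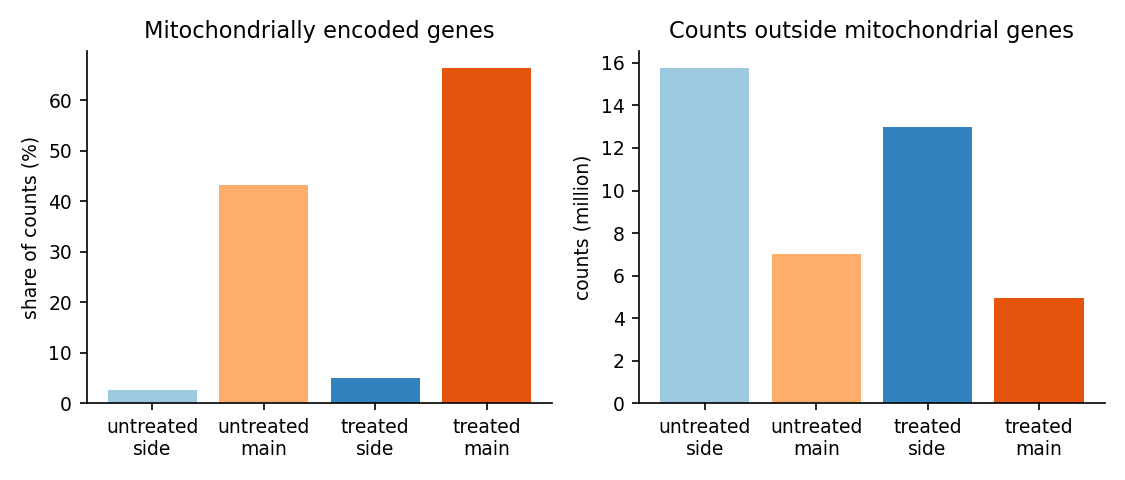
Share of counts in mitochondrially encoded genes (left, percent) and counts outside them (right), one bar per library. The share was 2.55% and 4.97% in the side-population libraries and 43.1% and 66.5% in the main-population libraries.

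The first comparison asks how AC220 with HHT changed gene expression across both populations. Genes of the cell cycle were lower after treatment, with DNA replication, mitosis and homologous recombination genes falling together. The mitotic kinase PBK (ENSG00000168078) fell by 4.81 on the log2 scale (SE 0.45, edgeR adjusted p = 0.000223). The replication licensing factor CDC6 (ENSG00000094804) fell by 3.81 (SE 0.36, edgeR adjusted p = 0.000223), and the ribonucleotide reductase subunit RRM2 (ENSG00000171848) fell by 3.64 (SE 0.32, edgeR adjusted p = 0.000223). Of heat shock, cholesterol synthesis and endoplasmic reticulum chaperone genes, 9 of 17, 7 of 22 and 4 of 18 fell. In the edgeR fit, 266 genes were higher and 471 lower after treatment, of 14457 tested, and 216 and 379 of these had a ratio of at least 2-fold in the same direction in both populations. The unadjusted p was under 0.05 for 2930 genes.

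Those calls come from 1 library per group. The fits that follow without the population term, or with a library left out, let the population difference into their spread or their values. Fewer calls there do not show that a call depends on 1 library. A fit without the population term called 0 genes, and fits without the untreated side, untreated main, treated side or treated main library called 11, 514, 0 and 0. With total counts as the scaling 12 genes were higher and 102 lower, with upper-quartile scaling 740 and 558, and without the untreated main library 304 and 210, so the balance of directions is not settled. Of 80 called genes followed one by one, 34 moved by over 1.5 times, 10 changed sign and 80 lost their call in some fit with a library left out.

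Of the 31 G1/S and DNA replication genes, 30 fell, and 31 did when adjusted over the list alone. MCM10 fell by 3.29 (SE 0.35) and DTL by a log2 fold change of -3.14 (SE 0.37), with edgeR adjusted p = 0.000288 and 0.000378. The list median was -2.14 in side cells and -2.17 in main cells, lower than that of every matched random list (percentile 0 in both). Of the 29 G2/M and mitosis genes, 24 fell, and 29 did when adjusted over the list alone. The median of that list was -3.40 in side cells and -1.47 in main cells, where 28 members were below 0. ASPM and DLGAP5, which act at the mitotic spindle, had log2 fold changes of -4.30 (SE 0.52) and -4.25 (SE 0.69). Cyclin A2 (CCNA2) had -3.60 (SE 0.37) and its kinase partner CDK1 had -3.45 (SE 0.38), and all 4 passed the edgeR test. DLGAP5 ran from -5.31 to -2.63 with a library left out. Of the 19 homologous recombination repair genes, 15 fell, and 18 did when adjusted over the list alone, with medians of -2.31 in side cells and -1.74 in main cells. BRIP1 had a log2 fold change of -3.65 (SE 0.45), EXO1 -3.11 (SE 0.40) and RAD54L -2.58 (SE 0.45), the last from -3.55 to -1.63 with a library left out.

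The lowest called fold changes were otherwise those of spindle and kinetochore genes. SKA1, SPC25, NDC80 and CKAP2L had log2 fold changes of -4.63 (SE 0.67), -4.58 (SE 0.92), -4.22 (SE 0.57) and -3.86 (SE 0.69). The kinase MELK had -3.91 (SE 0.52) and GTSE1 had -3.62 (SE 0.68). The cytidine deaminase APOBEC3B had -3.60 (SE 0.55), from -5.54 to -2.19 with a library left out.

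Among the 17 heat shock genes, 9 fell, and 14 did when adjusted over the list alone. HSPA8 (ENSG00000109971), the constitutive HSP70, fell from 1410 to 483 CPM in side cells and from 1100 to 354 in main cells, a log2 fold change of -1.59 (SE 0.28, edgeR adjusted p = 0.00425). HSPH1 had -2.10 (SE 0.30), the mitochondrial chaperonin HSPE1 -1.73 (SE 0.30) and FKBP4 -1.35 (SE 0.30). Of the 18 endoplasmic reticulum chaperone genes, 4 fell, namely PDIA4 at -2.19 (SE 0.29), SDF2L1 at -1.90 (SE 0.33), MANF at -1.42 (SE 0.32) and HSPA5 at -1.08 (SE 0.28). Adjusted over the list alone, 12 fell. Of the 22 cholesterol synthesis genes, 7 fell, and 15 did when adjusted over the list alone. The squalene epoxidase SQLE had -1.77 (SE 0.32) and ACAT2 had -1.73 (SE 0.34). Their medians in side and main cells were -0.88 and -1.11 for heat shock genes, -0.72 and -1.07 for endoplasmic reticulum chaperones and -1.10 and -0.83 for cholesterol genes, with percentiles of at most 0.01 among matched random lists.

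The targets of the drugs and their pathways had fewer called members. FLT3 (ENSG00000122025), the receptor that AC220 inhibits, had 283, 185, 207 and 124 CPM (scaled counts over the effective library size) in untreated side, untreated main, treated side and treated main cells, a log2 fold change of -0.51 (SE 0.28, edgeR adjusted p = 0.324), from -0.92 to -0.16 with a library left out. Of the 17 FLT3 and STAT5 target genes, 2 fell, the kinase PIM1 at -1.77 (SE 0.34) and cyclin D3 (CCND3) at -1.65 (SE 0.29), and 3 did when adjusted over the list alone. MYC (ENSG00000136997) had -1.51 (SE 0.43, edgeR adjusted p = 0.061). MCL1, which protects from apoptosis, had 0.01 (SE 0.29) and the homing receptor CXCR4 had 0.20 (SE 0.31), and neither passed the test. Fits with a library left out gave MCL1 values from -0.57 to 0.52 and CXCR4 values from -0.29 to 0.65. Of the 14 ERK pathway feedback genes, 2 fell, ETV5 at -1.72 (SE 0.45) and the ERK phosphatase DUSP6 at -1.70 (SE 0.42), with 1 up and 3 down adjusted over the list alone. With a library left out, DUSP6 ran from -2.67 to -0.56, PIM1 from -2.65 to -0.78 and MYC from -2.63 to -0.34. The proapoptotic BCL2L11 fell by 1.41 (SE 0.34) and was the called member of the 19 FOXO target genes and of the 13 BCL2 family genes, with 1 down and, for the BCL2 family, 1 up adjusted over each list alone.

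Among the 25 ATF4 amino acid response genes, 5 fell and 1 rose, with 9 and 3 when adjusted over the list alone. Serine synthesis genes PSAT1 and PHGDH had -2.17 (SE 0.33) and -2.04 (SE 0.36). The transporter SLC7A5 had -1.46 (SE 0.28) and the transfer RNA synthetases AARS and GARS had -1.35 (SE 0.28) and -1.25 (SE 0.28). The stress transcription factor DDIT3 rose by 1.38 (SE 0.35), and DDIT4 had 1.87 (SE 0.55, edgeR adjusted p = 0.0682), and with a library left out they ran from 0.16 to 2.84 and from 0.74 to 3.04. Of the 23 translation factor genes, EIF4EBP1 and EIF5A fell, at -1.30 (SE 0.28) and -1.17 (SE 0.28), 2 also when adjusted over the list alone. Of the 25 MYC-linked ribosome biogenesis genes and the 74 cytosolic ribosomal protein genes, 0 passed either adjustment. The ribosome biogenesis median was -0.66 in side cells, with 23 members below 0 (percentile 0), and -0.40 in main cells, with 20 below 0 (percentile 4.21), and the ribosomal protein medians were -0.06 and -0.03. NPM1 and NCL, abundant nucleolar proteins, had -0.94 (SE 0.28) and -0.80 (SE 0.27). The 20 DNA and histone methylation enzymes held 1 that fell, EZH2 at -1.23 (SE 0.30), the 21 glycolysis genes PGK1 at -1.37 (SE 0.29) and the 30 nuclear oxidative phosphorylation genes NDUFA4 at -1.27 (SE 0.30). Adjusted over each list alone these were 1, 3 with 1 up, and 1. PGK1 ran from -1.92 to -0.89 and NDUFA4 from -1.84 to -0.81 with a library left out.

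Genes that rose included the semaphorin SEMA3B (ENSG00000012171) at 3.56 (SE 0.36, edgeR adjusted p = 0.000288), the glutamate receptor subunit GRIK5 at 3.53 (SE 0.46) and RN7SK at 3.35 (SE 0.72). MYOM1, NHSL2, PRAM1 and the cyclin-dependent kinase inhibitor CDKN1C had 3.34 (SE 0.50), 3.33 (SE 0.60), 3.27 (SE 0.37) and 3.23 (SE 0.55). ANKRD24, CCR10, ZNF467 and NPAS1 lay between 3.01 and 3.22. With a library left out, SEMA3B ran from 2.10 to 5.17, PRAM1 from 1.82 to 4.99, CDKN1C from 1.80 to 4.86, CCR10 from 0.25 to 6.80, ANKRD24 from 0.57 to 6.06, GRIK5 from 1.33 to 6.20 and NPAS1 from 1.45 to 5.12. Of the 266 genes that rose, 99 were also called higher in main than in side cells, where independent sets would share 23. Their median GC content was 56.2%, against 49.1% for all tested genes and 45.5% for the genes that fell. Of the 28 replication-dependent histone genes, 2 rose, HIST1H2BG at 2.74 (SE 0.62) and HIST1H2AE at 1.99 (SE 0.52), and 5 did when adjusted over the list alone. With a library left out these ran from 0.33 to 6.13 and from 0.35 to 3.69. The 13 mitochondrially encoded protein genes held 4 that rose, MT-ND1, MT-ND5, MT-ND4 and MT-CYB at 1.12 (SE 0.27), 1.12 (SE 0.26), 1.03 (SE 0.26) and 1.00 (SE 0.27), and 10 did when adjusted over the list alone. The ribosomal RNAs MT-RNR1 and MT-RNR2 had 2.21 (SE 0.26) and 1.61 (SE 0.25). Without the treated main library, RN7SK had -3.21, MT-ND1 -2.16, MT-ND5 -2.43, MT-ND4 -2.32, MT-CYB -2.51, MT-RNR1 -3.32 and MT-RNR2 -4.13. That fit had no population term and set treated side cells against untreated side and main cells, so these values carry the population difference. Within side and main cells the ratios were 5.43 and 1.43 for RN7SK, 2.34 and 2.07 for MT-RNR1 and 1.43 and 1.79 for MT-RNR2.

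Other lists had 1 member that rose or 0. XPC of the 24 p53 target genes had 1.23 (SE 0.29), ATG14 of the 26 lysosome and autophagy genes 1.38 (SE 0.33) and TRAF1 of the 13 NF-kB and inflammatory genes 2.19 (SE 0.39), with 1 up adjusted over each list alone. TRAF1 ran from 1.12 to 3.47 with a library left out. CEBPE of the 14 primary granule and promyelocyte genes had 2.70 (SE 0.72), with 1 down in addition when adjusted over that list alone. ABCA7 of the 18 ABC transporter genes had 1.15 (SE 0.31), with 1 up adjusted over the list alone. Without the treated main library it had -0.05, in a fit with no population term. Of the 26 immediate early genes 0 were called, and 5 rose and 1 fell when adjusted over the list alone. JUN had 2.91 (SE 0.94, edgeR adjusted p = 0.0932), PPP1R15A 1.75 (SE 0.53) and NR4A1 1.61 (SE 0.66), and leaving out a library took these as low as 0.38, 0.29 and 0.21. Of the 19 interferon-stimulated genes 0 were called, and 4 rose when adjusted over the list alone. No member was called by either adjustment among the 17 MLL fusion target, 16 monocyte and macrophage, 13 stem and progenitor, 17 Wnt, Notch and Hedgehog, 15 hypoxia and 14 adhesion and homing genes.

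**Figure D2:**
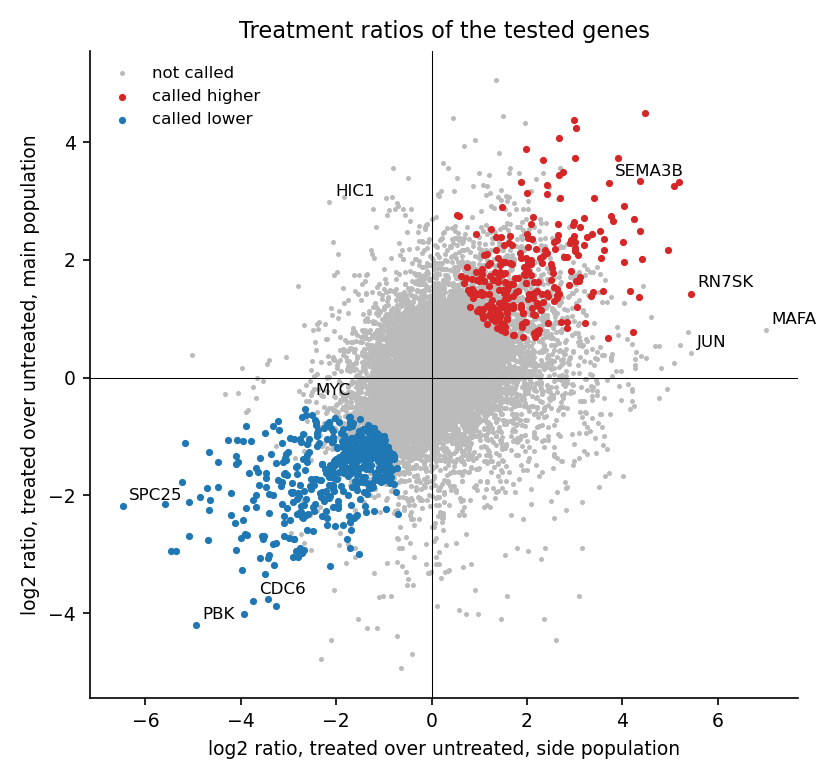
Log2 ratio of treated to untreated cells in the main population (vertical) against that in the side population (horizontal), one point per tested gene, with the 266 genes called higher and the 471 called lower coloured. Called genes lie in the quadrants where both ratios have the same sign, and MAFA and JUN lie far to the right near 0 on the vertical axis.

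The second comparison asks how side-population cells differed from main-population cells across both treatments. The lowest fold changes in side cells belonged to small nuclear RNAs and mitochondrial ribosomal RNAs. Most genes lower in side cells were protein-coding nuclear genes, as were 11745 of the 14457 genes tested. In a separate fit of those genes alone, 863 were lower and 126 higher in side cells. MT-RNR2 (ENSG00000210082), the large mitochondrial ribosomal RNA, had a log2 fold change of -6.72 (SE 0.31, edgeR adjusted p = 4.7e-08). RNU5E-1, a spliceosomal RNA, had 130 and 182 counts in main cells and 0 in side cells. With TMM scaling it was at least 295-fold higher in main cells, against a floor of 3 counts over the side group. That bound holds for TMM scaling alone. Of the genes higher in side cells, TXNIP (ENSG00000117289), an inhibitor of thioredoxin and of glucose uptake, had 2.32 (SE 0.34, edgeR adjusted p = 0.000837). In the edgeR fit, 262 genes were higher and 1250 lower in side cells, and 131 and 983 of them had a ratio of at least 2-fold in the same direction in both treatments. The unadjusted p was under 0.05 for 3849 genes.

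Without the treatment term, 5 genes were called, and without the untreated side, untreated main, treated side or treated main library 295, 26, 979 and 0. Of 71 called genes followed one by one, 33 moved by over 1.5 times, 5 changed sign and 71 lost their call in some such fit. Those fits had no treatment term, so the effect of treatment enters their spread or their values. Scaling by total counts turned the balance, with 2398 genes higher and 137 lower in side cells. That scaling put the median side over main log2 ratio of all tested genes at 0.93 in untreated and 1.91 in treated cells.

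Apart from RNU5E-1, with 0 counts in side cells, the lowest fold changes of genes named by the rule belonged to RNU1-1 at -8.66 (SE 0.89), RNU11 at -7.77 (SE 0.64), RN7SK at -7.57 (SE 0.81) and RNVU1-18 at -7.46 (SE 0.61). These sizes rest on few counts in untreated and treated side cells, 0 and 1 for RNU1-1, 0 and 12 for RNU11 and 0 and 21 for RNVU1-18, and leaving out a library took RNU11 to -12.47 and RNVU1-18 to -12.84. SCARNA17, SCARNA10, MT-RNR1 and RNU4ATAC had -6.97 (SE 0.86), -6.62 (SE 0.63), -6.51 (SE 0.32) and -6.34 (SE 0.68). Few counts in untreated and treated side cells also underlie SCARNA17 (0 and 4), SCARNA10 (3 and 4) and RNU4ATAC (1 and 8). Higher in side cells were C5orf51 at 2.44 (SE 0.38), C2orf44 at 2.30 (SE 0.58), DDX20 at 2.14 (SE 0.37), the transcription cofactor NRIP1 at 1.96 (SE 0.31) and the linker histone H1F0 at 1.91 (SE 0.53). Leaving out a library took C2orf44 to 1.43 and H1F0 to 1.19 at the lowest. The zinc finger genes ZNF189, ZNF175 and ZNF45 had 2.27 (SE 0.38), 2.04 (SE 0.48) and 2.02 (SE 0.40). APOBEC3B had 2.12 (SE 0.54), with ratios of 1.84 in untreated and 2.46 in treated cells. Without the untreated side library it had -0.58, in a fit with no treatment term that carries its fall after treatment. Median GC content was 42.9% for the genes higher in side cells and 56.9% for those lower, with 49.1% over all tested genes.

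All 13 mitochondrially encoded protein genes were lower in side cells, with MT-CO1 at -4.62 (SE 0.28) and MT-ND5 at -4.48 (SE 0.30). Of the 28 histone genes, 9 were lower, including HIST1H4C at -3.89 (SE 0.53) and HIST1H2BG at -3.37 (SE 0.62), and of the 74 ribosomal protein genes, 17 were lower, including RPS15 at -2.05 (SE 0.29), RPL28 at -2.02 (SE 0.29), RPL36 at -1.82 (SE 0.29) and RPL35 at -1.69 (SE 0.28). Counts adjusted over these lists alone were 13, 9 and 17. HIST1H2BG ran from -6.27 to -1.50 with a library left out. The histone median was -1.39 in untreated cells and -1.58 in treated cells (percentiles 0.24 and 0). Scaled by total counts it was 0.20 in treated cells (percentile 0), where the median of all tested genes was 1.91. Of the 25 ribosome biogenesis genes, 6 were lower, including the helicase DDX21 at -1.54 (SE 0.31), with 1 higher and 7 lower adjusted over the list alone. EEF1D was the called translation factor, at -1.44 (SE 0.28), 1 also adjusted over the list alone.

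The lists of RNAs added after the libraries had been seen moved the same way. Of 17 small RNAs without a poly(A) tail, 13 were lower in side cells by both adjustments, with a median log2 fold change of -4.95. After treatment RN7SK and RNU4-2 rose, the latter by 2.53 (SE 0.68), and 9 did when adjusted over the list alone. Without the treated main library RNU4-2 had -1.68, in a fit with no population term. Of 7 nuclear-retained long RNAs, KCNQ1OT1 and the paraspeckle RNA NEAT1 were lower in side cells, at -2.25 (SE 0.39) and -1.46 (SE 0.35), and 5 were adjusted over the list alone. Leaving out a library took KCNQ1OT1 to -0.99 and NEAT1 to -0.43 at the nearest to 0. KCNQ1OT1 and NEAT1 rose after treatment, by 1.82 (SE 0.39) and 1.43 (SE 0.35), 2 also adjusted over the list alone, and with a library left out they ran from 0.41 to 3.57 and from 0.38 to 2.57.

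The G2/M and mitosis list had 7 members higher in side cells and 0 lower. CCNB1 had 1.79 (SE 0.46), KIF20A 1.58 (SE 0.44), CDK1 1.36 (SE 0.36) and CCNA2 1.35 (SE 0.35), and 10 were higher and 1 lower adjusted over the list alone. Without the untreated side library, CCNB1 had 0.05, KIF20A -0.18, CDK1 -1.31 and CCNA2 -1.44. That fit had no treatment term, so the effect of treatment enters these values. The list median was 1.67 in untreated cells and -0.26 in treated cells (percentiles 100 and 1.25). Scaled by total counts the treated value was 1.56 (percentile 0.98), where the median of all tested genes was 1.91. In the G1/S list, 1 gene was lower in side cells, the checkpoint mediator CLSPN at -3.12 (SE 0.43), and in the recombination list XRCC3 and FANCA had -1.32 (SE 0.28) and -1.58 (SE 0.28), 1 and 2 also adjusted over each list alone. Nearest to 0 with a library left out, CLSPN had -1.59, XRCC3 -0.69 and FANCA -0.37.

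Of the 26 immediate early genes, 3 were lower in side cells, IER2 at -2.25 (SE 0.40), JUNB at -1.92 (SE 0.40) and ZFP36 at -1.15 (SE 0.34), with 9 lower and 1 higher adjusted over the list alone. Nearest to 0 with a library left out, IER2 had -1.33, JUNB -0.85 and ZFP36 -0.30. JUN had -2.58 (SE 0.94, edgeR adjusted p = 0.0975), and 0.11 without the untreated side library. The list median was -1.71 in untreated and -0.09 in treated cells (percentiles 0 and 17.8).

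Some ABC transporters export dyes and drugs, while other members of the list, ABCE1 and ABCF1 among them, are not exporters. ABCG2 (ENSG00000118777), the transporter most often tied to a side population, had 4 and 3 counts in untreated side and main cells and 2 and 3 in treated ones, and ABCB1 had 0 and 2, then 0 and 3. Neither was tested at this depth. Of the 18 measured members of the ABC transporter list, ABCE1 was higher in side cells at 0.95 (SE 0.28), and ABCA2, ABCA7 and ABCF1 were lower at -1.84 (SE 0.28), -1.66 (SE 0.31) and -1.22 (SE 0.33). Adjusted over the list alone, 2 were higher and 3 lower. Leaving out a library took ABCE1 to 0.51, ABCA7 to -0.80 and ABCF1 to -0.79 at the nearest to 0. The list median in untreated cells was -0.48 (percentile 1.61). Scaled by total counts it was 0.45 (percentile 1.36), where the median of all tested genes was 0.93. That scaling also moved ABCF1 to 0.18. The stem cell marker CD34 had 0 counts in every library, which allows up to 0.118 and 0.296 CPM in untreated side and main cells and 0.133 and 0.44 in treated ones. Of the 13 stem and progenitor genes, 0 were called, and the receptor KIT had 1.56 (SE 0.71, edgeR adjusted p = 0.178), with 0.27 at the lowest when a library was left out.

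FLT3 had 0.68 (SE 0.28), MCL1 0.77 (SE 0.29), CXCR4 0.50 (SE 0.31) and MYC 1.21 (SE 0.43) between populations, and none of them passed the test. Leaving out a library took FLT3 to 0.43, CXCR4 to 0.17 and MYC to -0.11 at the lowest. Higher in side cells were PIM1 at 1.26 (SE 0.34, and -0.06 without the untreated side library) of the FLT3 and STAT5 targets, CCR2 at 1.57 (SE 0.35) of the homing genes, and BCL2 at 1.08 (SE 0.29) of the BCL2 family and MLL fusion targets. The PIM1 ratios were 1.85 in untreated and 0.61 in treated cells. Other list members higher in side cells were CDKN1B, which like TXNIP is a FOXO target, the amino acid transporter SLC38A2, HERPUD1, CEBPA, NOTCH2, NDUFA9 and UQCRFS1, between 0.98 and 1.62. Lower were ADAM8 at -1.94 (SE 0.34), DDIT3 at -1.99 (SE 0.35), AZU1 at -1.57 (SE 0.31) and ASNS at -1.43 (SE 0.35). The signalling genes SOCS3, TNF and TRAF1 had -1.31 (SE 0.35), -1.24 (SE 0.35) and -1.78 (SE 0.38), and HSPA1B, BBC3 and ULK1 had -1.29 (SE 0.33), -1.14 (SE 0.32) and -1.05 (SE 0.31). At the nearest to 0 with a library left out, CCR2 had 0.88, BCL2 0.58, CDKN1B 0.70, SLC38A2 0.68, HERPUD1 0.45, NOTCH2 0.69, DDIT3 -1.10, TRAF1 -0.38 and BBC3 -0.52. Scaled by total counts, XRCC3, ZFP36, SOCS3, TNF, HSPA1B, BBC3 and ULK1 were between 0.08 and 0.34. Adjusted over each list alone, higher and lower members numbered 1 and 1 for FLT3 and STAT5 targets, ATF4 had 1 and 2, FOXO 2 and 1, BCL2 family 2 and 2, MLL fusion 2 and 0, granule 1 and 1, Wnt and Notch 1 and 0, and adhesion 1 and 1. For heat shock and methylation genes these were 0 and 1, for NF-kB genes 0 and 2, and for p53, endoplasmic reticulum, oxidative phosphorylation, cholesterol and lysosome genes 0 and 0. Members of the ERK feedback, monocyte, hypoxia, glycolysis and interferon lists had 0 calls.

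**Figure D3:**
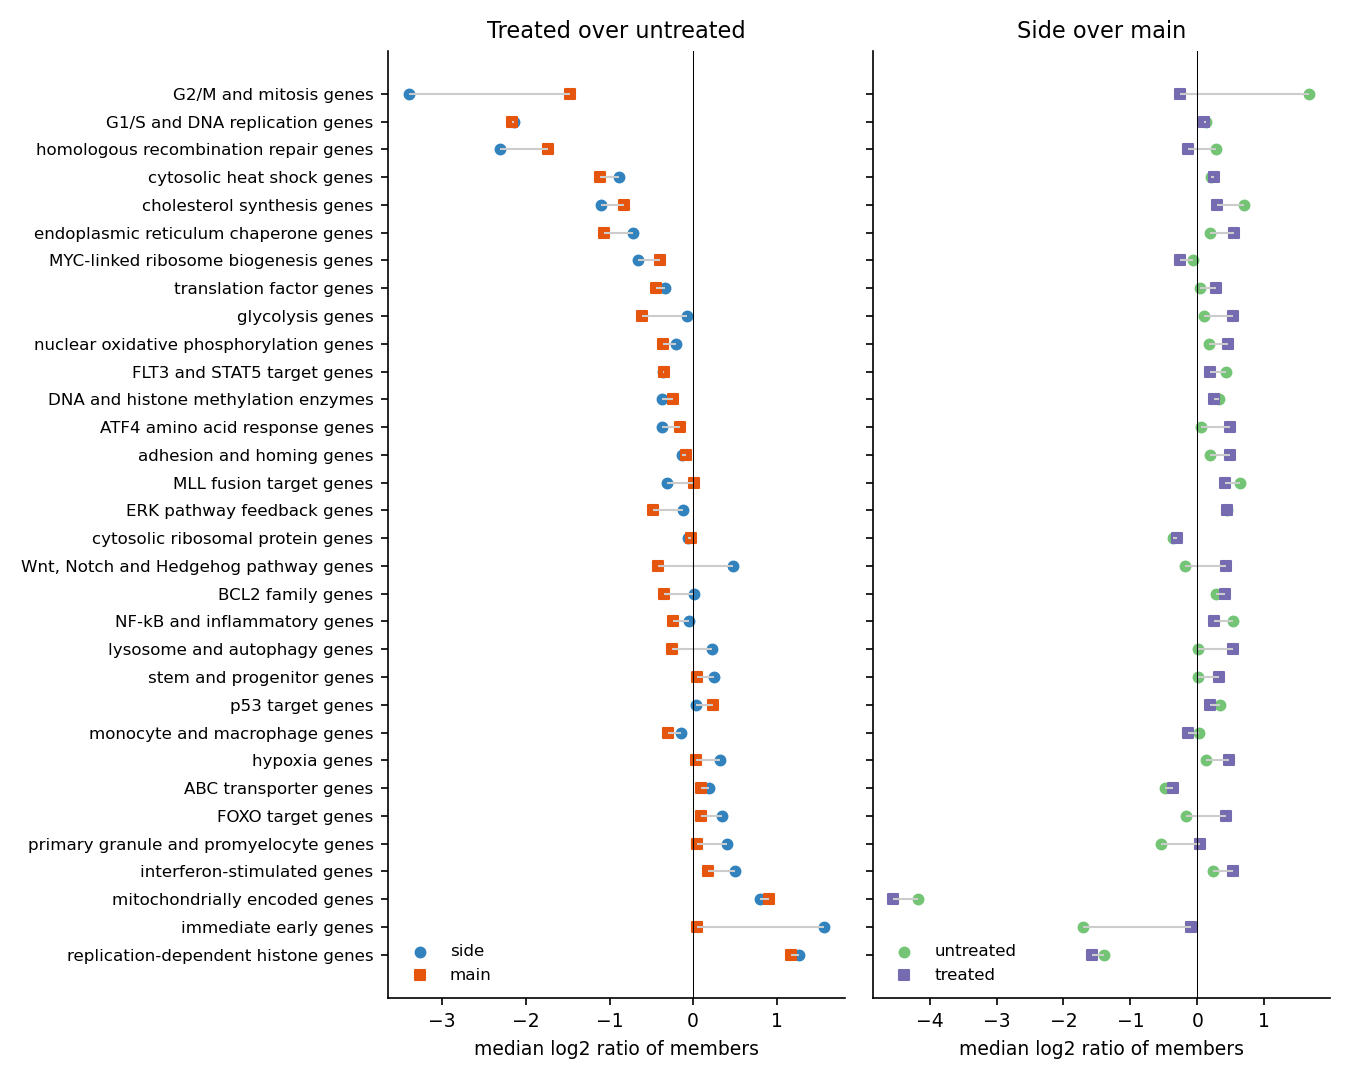
Median log2 ratio of the measured members of each of the 32 lists, treated over untreated (left) in side and main cells and side over main (right) in untreated and treated cells. DNA replication genes have medians of -2.14 and -2.17 on the left, and mitochondrially encoded genes have -4.17 and -4.54 on the right.

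Within the side population alone, 2401 genes were at least 2-fold higher and 1416 at least 2-fold lower after treatment, and within the main population 1662 and 1360. Between them, 740 were higher in both (276 if independent) and 528 lower in both (133 if independent). Across genes, which are not independent replicates, the ratios had Pearson r = 0.43 and Spearman rho = 0.42. Side cells differed from main cells in 1350 genes higher and 2705 lower when untreated and 1488 and 2636 when treated, with 325 higher and 1557 lower in both (139 and 493 if independent). Those ratios had r = 0.59 and rho = 0.54. Scaled by total counts, the main population had 419 genes higher and 5715 lower after treatment, and side cells had 6728 higher and 1243 lower than main cells when untreated, and 11234 and 401 when treated. By FPKM these splits were 89 and 2863, 4684 and 637, and 8721 and 271.

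The treatment ratios of the populations differed by a log2 value of at least 1 in 2055 genes with the larger ratio in side cells and 1619 with the larger ratio in main cells. The split was 6959 and 400 with total counts, 3874 and 211 with FPKM, and 1765 and 1930 with DESeq2 size factors. The difference was not tested. MAFA, a transcription factor with 1 count in the untreated side library, had 467 counts in the treated side library (counting interval of the log2 ratio 6.55 to 14.35) and a ratio of 0.81 in main cells. JUN (ENSG00000177606) had 5.44 (5.29 to 5.61) and 0.42 (0.36 to 0.48), and the JUN and MAFA ratios in main cells were -0.41 and -0.02 when scaled by total counts. RPPH1, ACPT, ZNF703 and F13A1 had 4.77, 3.72, 3.68 and 4.16 in side cells and -0.34, -1.62, -1.22 and -0.53 in main cells. RHBDL3, HIC1, CCR1, SPC25 and PIF1 had -5.03, -2.15, -2.81, -6.48 and -3.97 in side cells and 0.38, 2.98, 1.55, -2.19 and 0.17 in main cells. BCYRN1 had 60 counts in the untreated and 0 in the treated side library. With TMM scaling that was at least 17.8-fold lower, against a floor of 3 counts in the treated side library. Its ratio in main cells was -0.28, but by FPKM its difference between populations was 0.11. MYC had -2.56 (-2.68 to -2.45) in side cells and -0.40 (-0.65 to -0.15) in main cells. FLT3 had -0.45 and -0.58. The immediate early genes NR4A1 and KLF4 had 3.33 and 2.44 in side cells and -0.15 and -0.15 in main cells, and DDIT4 had 3.24 and 0.46. PPP1R15A had 0.29 in main cells and a ratio larger by 2.91 in side cells. With total counts, DDIT4 and PPP1R15A had -0.37 and -0.54 in main cells. That scaling put the median ratio of all tested genes in main cells at -0.81, which also bears on JUN and MAFA. The immediate early list had a median ratio of 1.57 in side cells (percentile 100) and 0.04 in main cells (percentile 71.0).

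**Figure D4:**
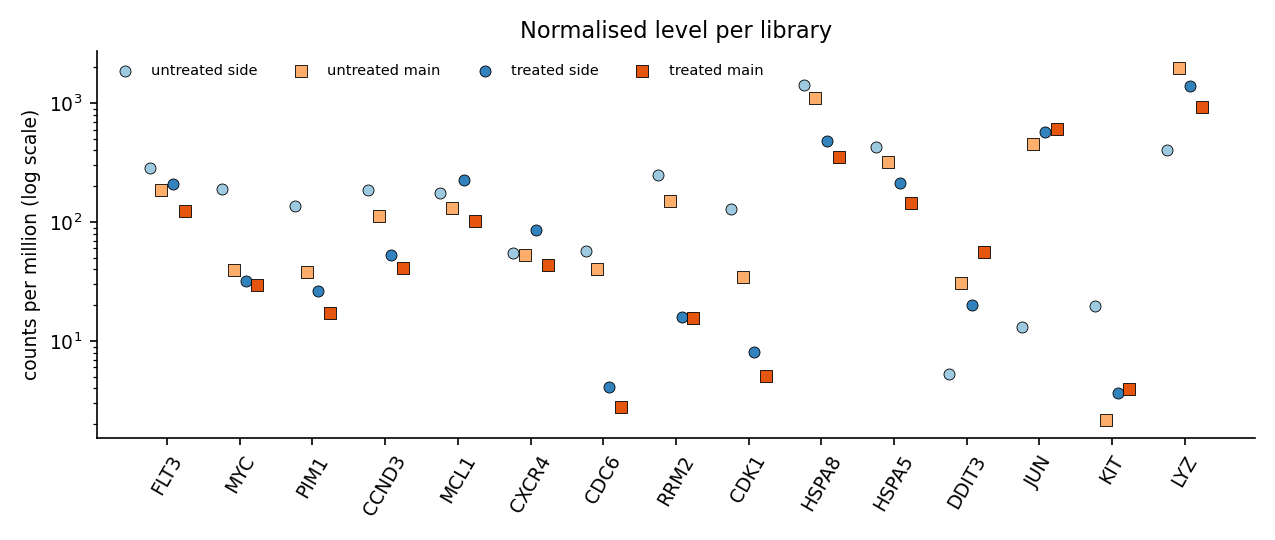
TMM-scaled CPM (log scale) of 15 named genes, with 1 point for each of the 4 libraries. CDC6, RRM2 and CDK1 lie below both untreated levels in both treated libraries, and JUN lies at 13.1 in untreated side cells and between 454 and 608 in the other libraries.

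Markers of other cell types were measured as a check of the cultures. The highest erythroid marker, SLC4A1, reached 0.44 CPM and the highest endothelial marker, PLVAP, 3.96. The fibroblast, B lymphocyte, epithelial and megakaryocyte sets reached 7.48 (FN1), 15.1 (IGLL1), 21.9 (KRT18) and 37.6 (ITGA2B). CD4, which monocytic cells also express, reached 257 in the lymphocyte set, and CSF3R, a receptor of myeloid progenitors, reached 387 in the neutrophil set. ITGA2B rose after treatment by 1.37 (SE 0.35), IL7R fell by 2.35 (SE 0.61), and CSF3R and MMP25 rose by 1.11 (SE 0.29) and 1.31 (SE 0.35) by the edgeR test. Leaving out a library took ITGA2B to 0.81 and MMP25 to 0.27 at the lowest. Without the treated main library CSF3R had -0.16, in a fit with no population term. Within populations, CSF3R went from 45.0 to 117 CPM in side cells and from 215 to 387 in main cells. CSF3R and MMP25 were lower in side cells at -1.99 (SE 0.29) and -1.60 (SE 0.35), and MMP25 had -0.68 at the nearest to 0 with a library left out. These 4 genes were named after their values were seen.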

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

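For the difference between populations, the tests on poly(A) selection and on mitochondrial RNA alone were chosen only after the result was seen, and the list behind the test on cytoplasmic RNA was made after the libraries had been seen, before its own values were. Both main libraries held more mitochondrial and small nuclear RNA. The histone list had a population median log2 fold change of -1.68, with percentiles of 0.24 and 0 in untreated and treated cells, as weaker poly(A) selection could give. The nuclear-retained RNAs had -1.46, as loss of cytoplasmic RNA from damaged cells could give, and both stay open, as does a difference between the populations themselves, which was not tested. A change of mitochondrial RNA alone leaves the small nuclear RNA, part of this same pattern, without an account. With scaling by counts outside the mitochondrial genes, the histone list still had medians of -1.23 and -1.24 in untreated and treated cells (percentiles 0.25 and 0). As that test was chosen after the result was seen, it is no independent support. It was not tested whether weaker poly(A) selection or loss of cytoplasmic RNA would lower 17 of 74 ribosomal protein genes in side cells. The same holds for the GC contents of 42.9% and 56.9%, and for the 13 mitochondrially encoded protein genes (population median -4.32). The ribosomal RNA RNA28S5 took 0.556% and 1.065% of counts in untreated side and main cells, and 0.610% and 1.482% in treated ones. RN7SK differed far more, at 0.000407% and 0.178%, then 0.0194% and 0.267%. These shares were not used in a test.

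For treatment, the tests on cell cycle genes were chosen only after the result was seen, and those on overlap before. Genes that rose overlapped genes higher in main cells 4.30 times as often as independent sets would, so that part of the rise could come from library composition. Genes that fell overlapped genes higher in side cells 3.05 times as often, but these were 26 of the 471 genes that fell, or 5.52%. For the G1/S list, the population median with TMM scaling was 0.0938 times the size of the treatment median. The composition difference between populations is therefore an unlikely source of its fall. The test does not cover composition that moved with treatment within a population, or other scalings. For the G2/M list that value was 0.345, between the bounds set, so composition could account for part of its fall and the test cannot tell. The side over main median of that list was 1.67 in untreated but -0.26 in treated cells, so 0.345 averages unlike differences.

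For the immediate early genes, both tests were chosen only after the result was seen. The list median in the untreated side library lay 0.94 below the lowest of the other libraries on the log2 scale, and its ratio in side cells was 1.57. A response of side cells and a low level in that library alone could each give these values, and 1 library per group cannot tell them apart.

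The differences that follow have opposite signs in the groups compared when scaled by TMM and were not tested. The treatment ratio in side cells minus that in main cells was 5.34 for ACPT (3.72 and -1.62). For CCR1 it was -4.36 (-2.81 and 1.55). CENPF had -3.70 (-3.40 and 0.30). Its ratio in main cells was -0.53 with total counts and -0.49 by FPKM, where the median of all tested genes was -0.81 and -0.49. The CXCR4 value was 0.92 (0.65 and -0.27). F13A1 had 4.69 (4.16 and -0.53). In HIC1 it was -5.13 (-2.15 and 2.98). KIT had -3.22 (-2.39 and 0.83).

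Further differences were likewise not tested. LYZ, the lysozyme gene, had 2.87 (1.78 and -1.09). For MCL1 it was 0.71 (0.36 and -0.35). RPPH1 had 5.11 (4.77 and -0.34). The ZNF703 value was 4.89 (3.68 and -1.22). The G2/M list median between populations was 1.67 in untreated and -0.26 in treated cells, a difference of 1.93. With total counts the treated value was 1.56, still low among matched lists (percentile 0.98), as the median of all tested genes was 1.91.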

How the results depend on the processing

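Treatment calls, 737 by edgeR, numbered 1158 with DESeq2 size factors, 114 with total counts, 1298 (740 higher, 558 lower) with upper-quartile scaling and 1215 without the filter. They were 0 without the population term and 0 to 514 with a library left out. A crossed split, added after the data had been seen, set untreated side and treated main cells against untreated main and treated side cells. It called 0 genes. Each side of that split held an untreated and a treated library, and the effects of treatment and population stayed in its spread. Its count therefore does not bear on the treatment calls. Population calls, 1512, numbered 2535 with total counts, 989 for protein-coding genes (added after the data had been seen), 5 without the treatment term and 0 to 979 with a library left out.

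Genes at 2-fold after treatment in side cells, 3817, numbered 2039 at 5 CPM, 9282 without a filter and 2073 by FPKM. In main cells 3022 became 6134 with total counts, 1631 and 9732. Between untreated populations 4055 became 7971, 2123 and 9703, and between treated ones 4124 became 11635, 2284 and 11909, with 8992 by FPKM and 2666 for protein-coding genes. Differences of ratios, 3674, became 7359 (6959 and 400), 1843 and 12172. The cause was not tested.

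With a library left out, treatment values ran from lowest to highest over -3.21 to 10.19 for RN7SK, -2.16 to 4.40 for MT-ND1, -2.32 to 4.42 for MT-ND4, -2.43 to 4.69 for MT-ND5, -2.51 to 4.52 for MT-CYB, -3.32 to 7.77 for MT-RNR1, -4.13 to 7.38 for MT-RNR2, -1.68 to 11.54 for RNU4-2, -0.0507 to 2.12 for ABCA7, -0.16 to 2.501 for CSF3R, -0.57 to 0.52 for MCL1 and -0.29 to 0.65 for CXCR4. The lowest came without the treated main library, or without treated side for MCL1 and CXCR4. Those fits had no population term, so the population difference enters their values. MCL1 had -0.37 with total counts and -0.0878 without a filter, and CXCR4 -0.18 with total counts.

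Population values ran over -0.58 to 5.29 for APOBEC3B, -5.34 to 0.11 for JUN, -1.31 to 3.71 for CDK1, -1.44 to 3.85 for CCNA2, 0.0494 to 3.25 for CCNB1, -0.18 to 2.85 for KIF20A, -0.0556 to 2.31 for PIM1 and -0.11 to 2.46 for MYC, turning without untreated side except for CCNB1. Those fits had no treatment term, so the effect of treatment enters their values. With total counts the population values turned for ABCF1 (0.18), SOCS3 (0.0834), HSPA1B (0.11), BBC3 (0.25), XRCC3 (0.0799), TNF (0.16), ZFP36 (0.24) and ULK1 (0.34).

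Ratios in main cells with total counts and FPKM were -0.0159 and -0.012 for MAFA, -0.41 and -0.41 for JUN, -0.54 and -0.54 for PPP1R15A, -0.53 and -0.49 for CENPF and -0.37 and -0.32 for DDIT4. The BCYRN1 difference was 0.11 by FPKM. In main cells the median treatment ratio of all tested genes was -0.81 with total counts and -0.49 by FPKM. With total counts, medians turned for G2/M (1.56) and histone genes (0.20) in treated and ABC genes (0.45) in untreated cells. Their percentiles stayed low, at 0.98, 0 and 1.36, since that scaling put the median of all tested genes at 1.91 in treated and 0.93 in untreated cells. The cause of the BCYRN1 change was not tested.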

Other observations

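Gene ontology terms were tested after the data had been seen, over 1195 terms and 11157 genes, by one-sided Fisher exact tests with Benjamini-Hochberg adjustment. The p values treat genes as independent and the calls as given, so they measure no spread between libraries. The calls are those used for the lists above. Genes that fell after treatment by edgeR were in excess in 67 terms, among them mitotic cell cycle with 114 of 374 genes (adjusted p = 3.84e-68), DNA replication with 58 of 142 (adjusted p = 3.52e-41) and DNA repair with 58 of 271 (adjusted p = 2.57e-24). Genes lower in side cells were in excess in 10 terms, with 24 of 97 respiratory electron transport chain genes (adjusted p = 1.86e-05), 13 of them mitochondrially encoded, and 18 of 91 translational elongation genes (adjusted p = 0.00874). Genes that rose after treatment and genes higher in side cells were in excess in 0 terms. The nuclear members of that chain included 11 of 84 lower in side cells, and the fixed list of 30 nuclear oxidative phosphorylation genes had 2 higher, 0 lower and a median log2 fold change of 0.32.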
